A study of Glycine max with 4 samples.

How the data were processed

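Genomic DNA from leaf tissue of 4 soybean (Glycine max) fast-neutron mutant individuals was compared with DNA of their wild-type parents on 2-colour oligonucleotide arrays (array comparative genomic hybridisation). Per the labels, about 90 mg of tissue was used per extraction and 500 ng of DNA per labelling reaction, the mutant was labelled with Cy3 (green) and the wild type with Cy5 (red), and no dyes were swapped. G15FN-109-1 was hybridised against G00-3880, and G15FN-12-1, G15FN-23-3 and G15FN-54-3 against G00-3213. Each mutant was measured on 1 array, so there are no replicates, and slide, scan and mutant cannot be told apart.

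Images came from a NimbleGen MS 200 scanner and were read with Agilent Feature Extraction 12.0.0.7 with its CGH protocol, per the file headers. The array design is named Gmaxv275_phytozomev10 in the headers, which leave the genome build field empty. The build behind the probe positions is therefore hinted at only by the design name, and coordinates are those of the array design. The processed signals are intensities that Feature Extraction had already background-subtracted, detrended and scaled by 1 linear factor per dye, without a lowess term, per the file headers. The deposited log ratio is a log10 of red over green, and it matched the processed signals to within 0.00001 on the log2 scale at 99.7% of probes on each array. The authors' value table holds log2 values. Set against the scanner output it was log2 of green over red, mutant over wild type, with a slope of 1.00, not centred, with column medians of −0.0058, −0.0028, −0.00079 and −0.0031 for G15FN-109-1, G15FN-12-1, G15FN-23-3 and G15FN-54-3. Its scale, centring and direction were thus all settled from the scanner values. Spot flags for background, saturation and outliers are those deposited in the scanner output.

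Each array carried 951615 probes in 960745 spots, of which 913 probes were spotted 11 times and the rest once. Control spots and the 551, 182, 247 and 224 spots with outlier flags on the 4 arrays, in the order above, were left out, and saturated spots (18, 6, 3 and 5) were kept. Repeated spots of a probe were averaged, and their median SD was 0.073, 0.071, 0.060 and 0.061 on the log2 scale. Of the probes, 8054 were placed by the design on a sequence named Chr014 and were absent from the authors' value table. They were left out of the main analysis, which left 943523, 943520, 943517 and 943507 probes on 20 chromosomes with a median spacing of 477 bp. The median processed intensity was between 1047 and 1066 in green and between 1043 and 1062 in red. Between 0.856% and 1.11% of green spots and between 0.851% and 1.05% of red spots were not well above background.

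The value used throughout is the log2 ratio of processed mutant signal to processed wild-type signal, centred on the median of its array, with no loess or quantile step. A halving of signal is −1 on this scale, and a change from 2 copies to 3 is 0.58. The spread between neighbouring probes, a noise SD taken from their median absolute difference, was 0.16, 0.14, 0.13 and 0.11. Probes further than 3 SD from their 5-probe running median were first shrunk to that limit. Each chromosome was then divided by penalised least squares, solved exactly, with a penalty of 20 times the squared noise SD per change. A segment with at least 5 probes was called a loss at a mean of −0.5 or lower, a deep loss at −1.5 or lower, and a gain at 0.3 or higher. Called segments of the same direction with 3 or fewer probes between them were joined. Segment means were taken over the unshrunk values of their probes. Each array was also segmented after its probes had been put in random order, 10 times, to count the calls that independent noise makes. A segment was private to a mutant if no call of the same direction on another array overlapped at least 50% of it. Segments shared by the 3 arrays with G00-3213 were counted at an overlap of 50% of the shorter and set against 1000 random placements (a one-sided permutation test). Windows of 100 neighbouring probes outside called segments were counted as wide where their robust SD was over 1.5 times the median window of the array. The tails of the probe distribution were given as the values bounding the lowest and the highest 0.1% of probes.

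These settings, the alternatives and the rule for named segments were fixed before the data were examined. The rule took all called segments of a mutant in a direction if there were 10 or fewer, and otherwise the 5 longest and the 5 with the most extreme mean. In losses of very low signal the probes scattered by several log2 units, and the planned calling broke them into many short segments with gaps. A second way of calling was therefore chosen after seeing the data. It joined segments past a threshold with the next of the same direction where 3 or fewer probes lay between them, or where the probes between them averaged past the threshold, and it applied the probe minimum after the joining. Its calls are named regions here. Regions of the same direction with at most 15 probes between them form a cluster, and segments at most 0.5 Mb apart form a block; both groupings were also chosen after seeing the data. The report gives counts from the planned segments and describes the large events, and some short ones, as regions or clusters. These contain only part of the segments that the rule named, and some of the others are not described.

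Both ways of calling were tested on simulated data, in which 800 changes of known size were put into each array's shuffled probes. Probe values were first limited to within 1 log2 unit of 0, and changes of −5 were given added scatter between probes. The planned calling found between 22% and 30% of 5-probe changes of −5, and between 58% and 84% of 50-probe ones, with at least 50% of the change called. The second way found 100% of these. The implanted changes lay far apart, so whether it joins separate changes across unaffected probes was not tested. Either way found at least 96% of 5-probe changes of −0.9 and of 0.8, between 34% and 90% of 5-probe changes of 0.45, and at least 96% of 10-probe changes of 0.45. Calls away from the implanted changes numbered 1 or 2 per array. Limiting and shuffling the values remove extremes and runs from the background, so this count does not carry over to the real arrays.

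In a loss where mutant probes, or a gain where wild-type probes, were not well above background, the ratio is only a bound. A fold written with at least was computed with each dim probe set to no less than the lowest processed signal that the array called well above background. This bound holds only for the scanner's background correction and is open to dye bias, since no dyes were swapped. Normexp, which adds an offset, gave smaller folds in the large deep losses. No p-value was computed for any mutant, because 1 array against 3 cannot go below an exact p of 0.25.

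The alternatives fixed in advance changed the penalty (40 and 14), the probe minimum (10 and 3), the thresholds (−0.8 with 0.5, and −0.35 with 0.2), the background correction (normexp with an offset of 50), the source of values (the authors' value table), the treatment of dim and of saturated probes, the centring, the segmentation (a 5-state hidden Markov model), the shrinkage, the subtraction of each probe's median over the other 3 arrays, the joining, the overlap (10% and 90%), and the window size and ratio (50 probes, and a ratio of 2). Mean signals were not among the columns of the scanner output, so normexp was run on the median signals. Alternatives chosen after seeing the data were the calling of regions, the placement of the Chr014 probes on chromosome 14, and a filter that kept only segments with at least 50% of their probes above background in 1 of the channels.

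Genes were not placed in the regions. The gene table used here belongs to the assembly Glycine_max_v4.0, while the probes carry positions of another design, so an overlap with the 12 gene lists that had been fixed was not run. Calculations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and numba 0.67.0, and R 4.3.3 with limma 3.58.1 for normexp. Plots were drawn with Matplotlib 3.10.9.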

Results

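Fast neutrons break chromosomes and are used in plants to delete or rearrange stretches of DNA. The arrays compared leaf DNA of 4 soybean mutant individuals, G15FN-109-1, G15FN-12-1, G15FN-23-3 and G15FN-54-3, with DNA of the wild-type line each came from. The series concerns seed composition in varieties of the southern United States. The question of each comparison was which parts of the genome had lost or gained signal in the mutant. G15FN-109-1 was set against G00-3880 and the other 3 mutants against G00-3213. Each mutant had 1 array, there were no replicates, and the error given below is the SD over the probes of a region. After filtering, between 943507 and 943523 probes per array were used, and the number of arrays limits the precision. Genes inside the regions were not analysed here, and positions are those of the array design.

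The 4 mutants carried very different sets of losses. G15FN-12-1 had deep losses over 5.32 Mb of chromosome 12, and G15FN-54-3 over 2.03 Mb of chromosome 10. G15FN-23-3 had a long stretch of chromosome 19 and G15FN-109-1 a stretch of chromosome 17 at a mean log2 ratio near −0.9. G15FN-109-1 also showed many short losses and gains side by side on chromosome 3. Losses exceeded gains in summed length on each array. Called losses covered 2.07 Mb in G15FN-109-1, 2.56 Mb in G15FN-12-1, 3.41 Mb in G15FN-23-3 and 1.01 Mb in G15FN-54-3, against 547 kb, 83.1 kb, 344 kb and 204 kb of gains. When losses were joined across their gaps as regions, they covered 3.03, 5.74, 3.47 and 2.55 Mb. In random probe order the same calling gave on average between 0.1 and 0.6 losses and between 0.2 and 0.6 gains per array. Random order removes the correlation between neighbouring probes, so calls from correlated noise are not counted there.

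**Figure D1:**
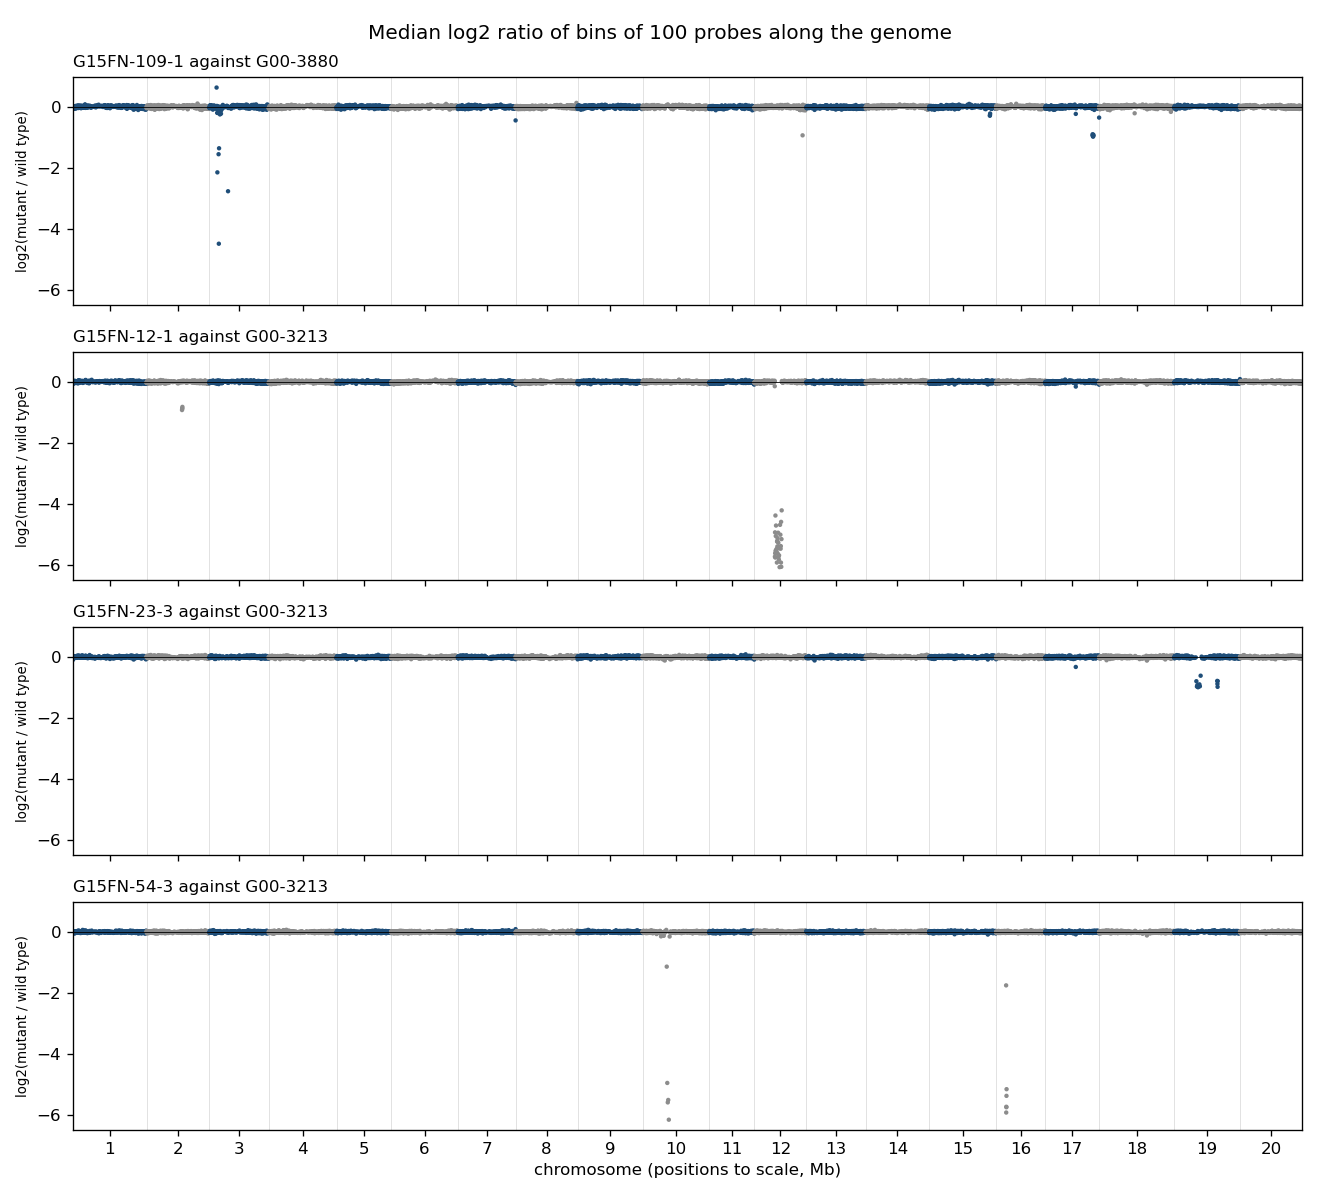
Log2 ratio of mutant to wild-type signal along the 20 chromosomes, 1 panel per mutant, with each point the median of 100 neighbouring probes. The deep losses of G15FN-12-1 on chromosome 12 and of G15FN-54-3 on chromosomes 10 and 16, and the shallower loss of G15FN-23-3 on chromosome 19, stand apart from values near 0.

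G15FN-12-1 had lost 1 large part of chromosome 12. A cluster of 5 loss regions ran from position 15835606 to 21155493, a span of 5.32 Mb with 3376 probes, of which 26 lay between the regions. Its mean log2 ratio was −5.0 (SD 2.05 over probes), against 0.02, 0.01 and 0.01 on the arrays of G15FN-109-1, G15FN-23-3 and G15FN-54-3. Of its probes, 34.3% were well above background in the mutant and 99% in the wild type, so mutant signal was at least 16.8-fold lower on the scanner's values. Just before it, 2 more regions between 15738343 and 15803432 had a mean of −5.31. The longest pieces inside the cluster were regions of 2332 kb (−4.90, 1664 probes) and 2263 kb (−5.09, 1178 probes).

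A second event of G15FN-12-1 lay on chromosome 2 between 27372982 and 27732218. Its 3 regions spanned 359 kb with 371 probes, and their mean was −0.87 (SD 0.22), against values from −0.01 to 0.01 on the other arrays. A short loss region of 6 probes on chromosome 17, from 30589387 to 30591921, had a mean of −4.91 (SD 1.73). The planned calling did not call it. Of the 12 called gains of this mutant, the one with the highest mean lay on chromosome 2 from 14654921 to 14667939, at 1.10 (SD 0.26, 10 probes). A gain of 20 probes on chromosome 15 from 46941257 to 46963118 had a mean of 0.35, but 20% of its wild-type probes were above background and its sign turned with normexp background correction, to −0.14. In all, 154 losses and 12 gains were called in G15FN-12-1, of which 133 losses were deep. Normexp left 3 gains, and leaving out probes dim in the wild type left 4. The 136 loss segments of chromosome 12 between 15801213 and 21151448 are fragments of the event described above, and joined as regions the losses of this mutant numbered 26. With normexp the 5 regions of the large cluster had means between −2.14 and −1.93.

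G15FN-54-3 had 2 large deep losses. On chromosome 10, 1 region ran from 18745626 to 20771558, a span of 2.03 Mb with 509 probes, at a mean of −4.82 (SD 2.07). On chromosome 16, 1 region ran from 7703354 to 8063984, a span of 361 kb with 541 probes, at a mean of −5.31 (SD 1.88). Depth varied inside the chromosome 10 region, where 45 probes from 18805187 to 18868413 had a mean of −2.46 with 86.7% of mutant probes above background. The other 3 arrays averaged 0.02 in both regions. All wild-type probes of both regions were above background, against 46.6% and 29.8% of mutant probes, so mutant signal was at least 17.3-fold and 19.4-fold lower on those values. With normexp the means were −2.27 and −2.17.

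Smaller loss regions of G15FN-54-3 included 16 probes on chromosome 13 from 13950649 to 13967045, at −2.94 (SD 1.79). A further 2 regions on chromosome 10 between 14502645 and 14635883 had a mean of −1.39 (SD 1.26). In all, 60 losses, 43 of them deep, and 25 gains were called in this mutant, and joined as regions the losses numbered 20. No gain had a mean above 0.77, and in 16 of the 25 gains fewer than 50% of the probes were above background in either channel. Leaving out probes dim in the wild type left 1 gain, and normexp left 0.

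**Figure D2:**
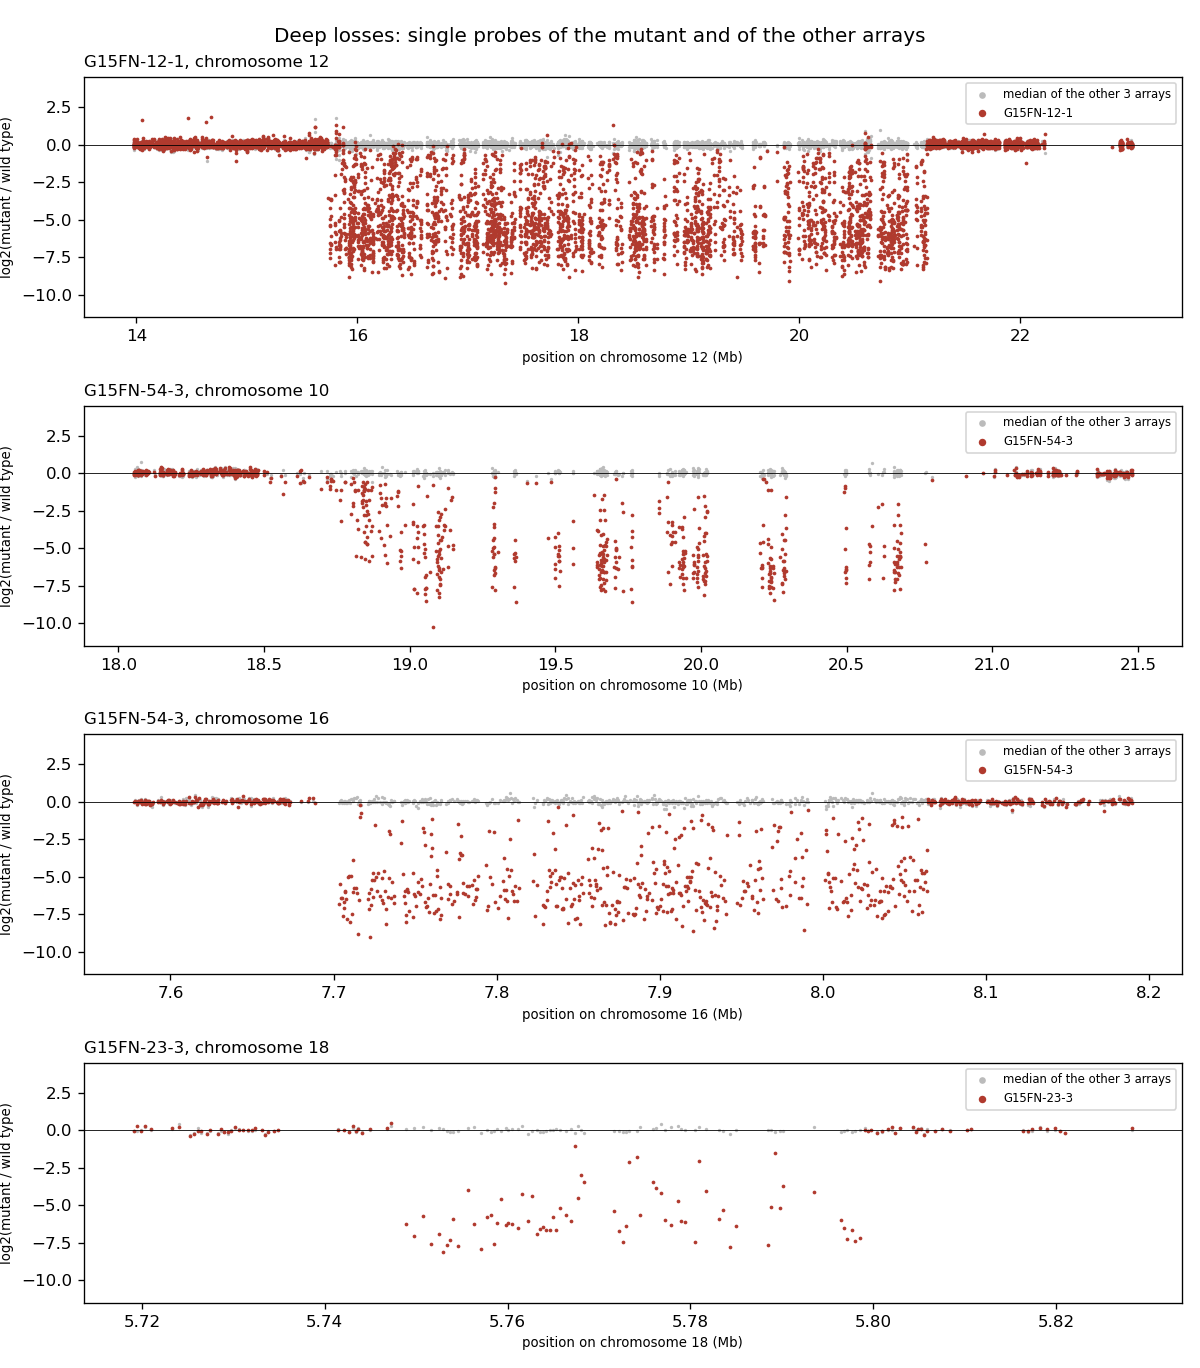
Log2 ratio of mutant to wild-type signal of single probes (vertical axis) against position in Mb (horizontal axis) around 4 deep losses, with the mutant in colour and the median of the other 3 arrays in grey. Inside each loss the mutant's probes fall far below 0 with a wide scatter while the grey points stay near 0.

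G15FN-23-3 had a long, shallow loss on chromosome 19. A cluster of 4 regions ran from 17157014 to 20136032, a span of 2.98 Mb with 925 probes, at a mean of −0.91 (SD 0.30), against 0.03, 0.02 and −0.00 on the arrays of G15FN-109-1, G15FN-12-1 and G15FN-54-3. The 4 regions had means of −0.92, −0.91, −0.93 and −0.89. Further along the same chromosome, 349 probes from 33169078 to 33573063 had a mean of −0.86 (SD 0.26), and on chromosome 7, 23 probes from 24273338 to 24320889 had a mean of −0.85 (SD 0.20).

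Besides these, G15FN-23-3 had 1 deep region of 73 probes on chromosome 18, from 5748925 to 5798644, at −5.70 (SD 1.62). All of its wild-type probes and 28.8% of its mutant probes were above background, so mutant signal was at least 29.4-fold lower on the scanner's values. The bound does not hold for normexp, with which the mean was −2.33. In all, 29 losses and 30 gains were called in this mutant. The longest gain by position, on chromosome 4 from 24058304 to 24228904 (0.47, 10 probes), had 10% of its wild-type probes above background. A gain on chromosome 2 from 14654921 to 14674495 had 19 probes, all above background, at 0.70 (SD 0.53). Normexp left 4 gains, and a penalty of 40 left 5.

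G15FN-109-1 had 1 long loss on chromosome 17 and many short, opposed changes elsewhere. The chromosome 17 loss ran from 36567596 to 37248640, a span of 681 kb with 817 probes, at a mean of −0.90 (SD 0.25), against 0.01 on the other 3 arrays. Losses of similar depth lay on chromosome 14 from 47864568 to 47880928 (−1.0, SD 0.15, 22 probes), on chromosome 17 from 30719270 to 30733485 (−0.90, SD 0.20, 19 probes), and on chromosome 12 from 37223120 to 37289194 (−0.94, SD 0.88, 100 probes). A gain on chromosome 2 from 5206464 to 5219843 had a mean of 1.45 (SD 0.26, 23 probes), or 2.73-fold, against 0.03, 0.01 and 0.00 on the other arrays.

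**Figure D3:**
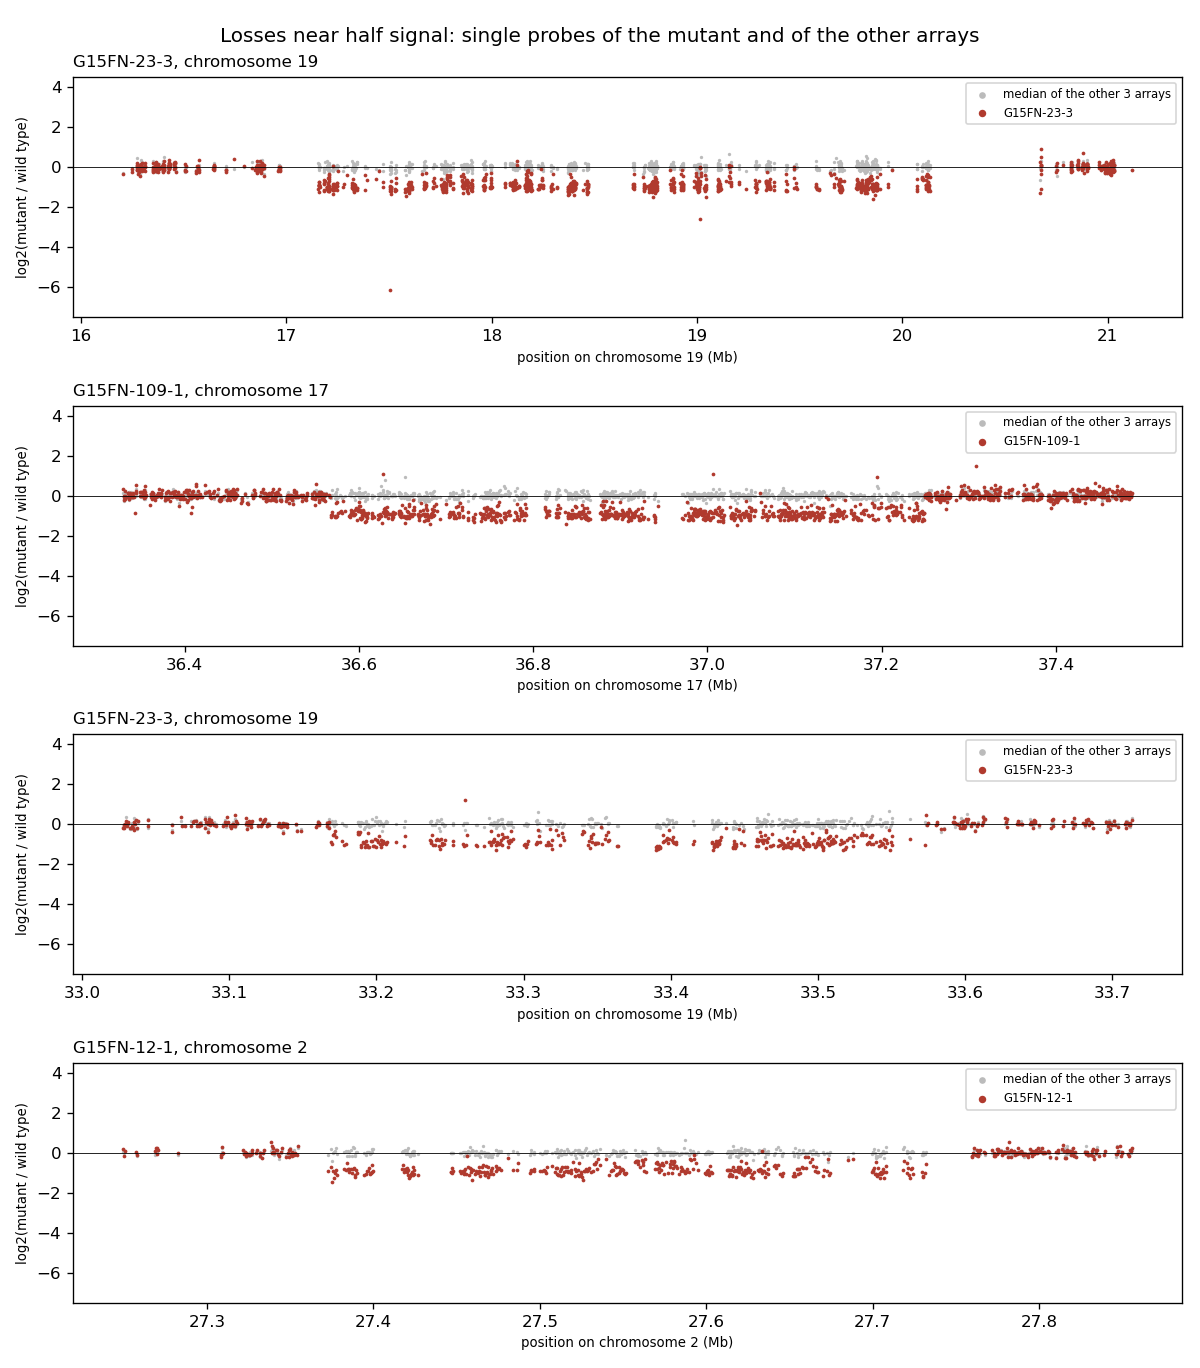
Log2 ratio of mutant to wild-type signal of single probes (vertical axis) against position in Mb (horizontal axis) around shallower losses of G15FN-23-3, G15FN-12-1 and G15FN-109-1, with the mutant in colour and the median of the other 3 arrays in grey. The mutant's probes form a narrow band near −0.9 inside each loss.

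Chromosome 3 of G15FN-109-1 held 63 of its called segments, 47 losses and 16 gains, and 49 of them lay between 5422359 and 9204137. The called segments covered 21.6% of that block. Its longest loss region, 376 kb from 7080835 to 7456709 with 217 probes, had a mean of −3.95 (SD 2.12), and 96 probes from 6144651 to 6234379 had a mean of −3.75 (SD 2.22). Outside the block, 62 probes from 14289416 to 14467004 had a mean of −4.84 (SD 2.09), and the lowest segment, from 11892383 to 11899612, had a mean of −6.55. Gains on the same chromosome reached higher values than on any other array. The 29 probes from 5522975 to 5578172 had a mean of 3.28 (SD 1.67), and 40 probes from 36067249 to 36090004 had a mean of 4.69 (SD 2.01). In the latter all mutant probes and 35.0% of wild-type probes were above background, so mutant signal was at least 13.1-fold higher on the scanner's values. Normexp gave 2.98 and 1.81 for these gains, leaving out probes dim in the wild type gave 2.80 for the second, and normexp gave −2.11 and −2.20 for the losses from 7080835 and 14289416.

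Chromosome 12 of G15FN-109-1 showed a smaller group of the same kind, 7 losses and 4 gains between 36438655 and 38018401, with a gain of 5.26 over 10 probes from 37319176 to 37327205. In this gain 30% of wild-type probes were above background, so that on the scanner's values mutant signal was at least 15.2-fold higher. In several gains of this mutant a few probes carried the mean. The 40 probes on chromosome 8 from 46832526 to 46857833 had a mean of 0.59 and a median of 0.09, and the 59 probes on chromosome 12 from 37541409 to 37578251 had a mean of 0.67 and a median of 0.10. With normexp neither was called, while their means over the same probes were 0.302 and 0.271, against the gain threshold of 0.3. In all, 128 losses and 55 gains were called, and in 50 of the losses fewer than 50% of the probes were above background in either channel. Leaving out probes dim in the wild type left 72 losses, and requiring 10 probes left 31 losses and 18 gains.

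**Figure D4:**
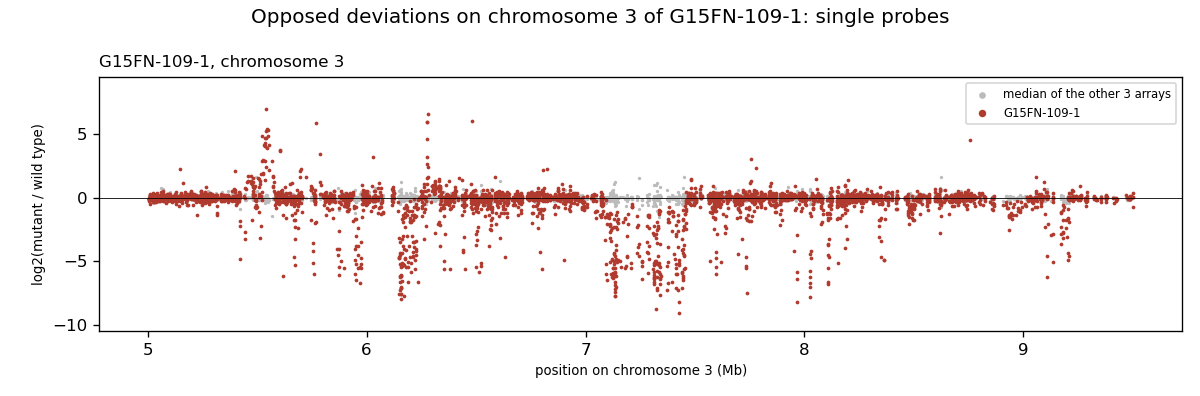
Log2 ratio of mutant to wild-type signal of single probes (vertical axis) against position on chromosome 3 in Mb (horizontal axis), with G15FN-109-1 in colour and the median of the other 3 arrays in grey. Stretches far below 0 alternate with stretches near 0 and with a peak above 0 near 5.5 Mb.

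Most called segments were private, 455 in all: 124 losses and 54 gains in G15FN-109-1, 146 and 8 in G15FN-12-1, 22 and 28 in G15FN-23-3, and 51 and 22 in G15FN-54-3. A private segment may still overlap a call on another array over a smaller part, or a call of the opposite direction. With an overlap of 10% the private count was 454. Some private segments also deviated on another array in the same direction below the threshold. Fragments of large losses make up much of the private count, 136 segments on chromosome 12 of G15FN-12-1, and 20 on chromosome 10 and 22 on chromosome 16 of G15FN-54-3. Each pair of arrays shared between 4 and 10 segments, and pairs with different parents 4 or 5. Random placement gave between 0.24 and 0.57 per pair on average and at most 4. The 3 arrays with G00-3213 as wild type shared 6 losses and 0 gains. Random placement of the segments gave 0.001 shared segments on average and 1 at most (one-sided permutation test, p = 0.001, the smallest that 1000 placements can give). Random placement takes into account neither the 1 wild-type line that the 3 arrays share nor signal common to all arrays. Outside called segments every 2 arrays were correlated (r from 0.21 to 0.46), also those with different parents. The test therefore cannot tell a shared wild-type line from an effect of the probes. All 6 were short, with 5 to 10 probes. The count of shared segments was 2 with normexp, 1 with a minimum of 10 probes and 10 with a minimum of 3.

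Of the 6 shared losses, 4 were also called on the array of G15FN-109-1, which used the other parent. They lay on chromosome 12 from 27953733 to 27956199 and from 32527746 to 32529343, on chromosome 13 from 6338782 to 6340759, and on chromosome 20 from 5102694 to 5105503. The chromosome 20 loss had means of −1.03, −1.1 and −0.93 on the arrays of G15FN-12-1, G15FN-23-3 and G15FN-54-3, and −1.05 on that of G15FN-109-1. A loss on chromosome 12 from 39184790 to 39194269 was called only on the 3 arrays with G00-3213, at −0.55, −0.59 and −0.94 against −0.08 in G15FN-109-1. The sixth, on chromosome 9 from 33306681 to 33309160, had means between −0.65 and −0.44 on those arrays and −0.23 in G15FN-109-1.

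**Figure D5:**
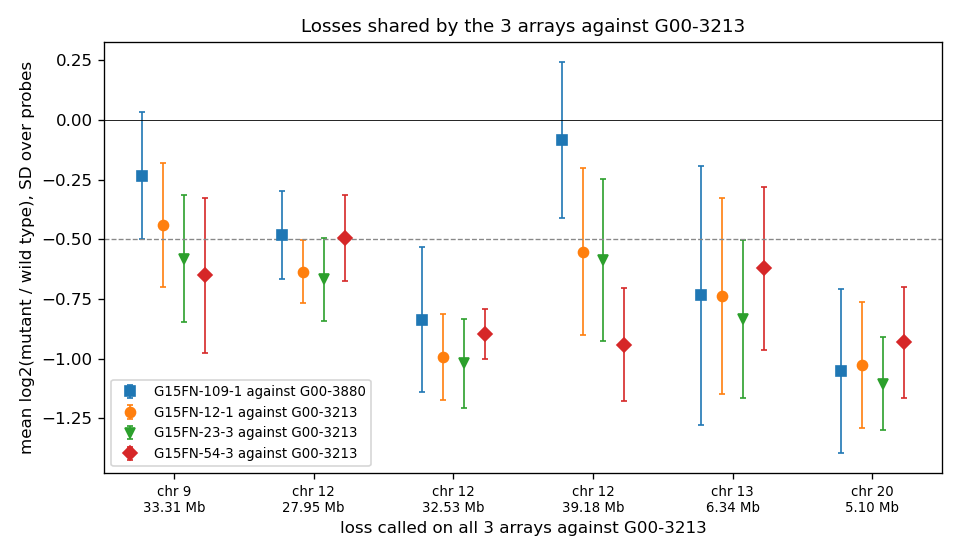
Mean log2 ratio of mutant to wild-type signal (vertical axis) of the 6 losses shared by the arrays with G00-3213, 1 point per array, with error bars showing the SD over probes and a dashed line at the loss threshold of −0.5. At 4 of the 6 positions the array of G15FN-109-1 lies beside the other 3.

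A gain on chromosome 2 from 14654921 to 14674495 was called in G15FN-12-1 and G15FN-23-3, with means over its 19 probes of 0.78 and 0.70. The same probes had means of −0.12 in G15FN-109-1 and −0.03 in G15FN-54-3, and all were above background in the wild type. With 1 array per mutant, the difference was not tested.

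As measured, losses reached further from 0 than gains on each array. The lowest segment mean was −6.55 in G15FN-109-1, −7.70 in G15FN-12-1, −6.37 in G15FN-23-3 and −7.11 in G15FN-54-3, and the highest 5.69, 1.10, 0.76 and 0.77. The 0.1 percentile of probes was −1.75, −6.43, −1.03 and −2.10, and the value that the highest 0.1% of probes passed was 1.17, 0.87, 0.87 and 0.90. In G15FN-109-1 both extremes are bounds, since 21.4% of mutant probes of the lowest segment and 16.7% of wild-type probes of the highest were above background, and their order is not settled there.

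Windows in which single probes scattered widely outside the called segments numbered 57 of 9399 in G15FN-109-1, 19 of them on chromosome 3 and 9 on chromosome 12. G15FN-12-1 had 31, of which 18 lay on chromosome 12, G15FN-23-3 had 12 and G15FN-54-3 had 18. Of these, 28, 18, 1 and 8 overlapped a loss region. The 18 of G15FN-12-1 on chromosome 12 lay between 15703117 and 21208539, in or at the edges of its large loss, parts of which the planned calling left out. With windows of 50 probes the counts were 261, 181, 156 and 177. With a ratio of 2 they were 14, 18, 2 and 7, and G15FN-12-1 then had the most. Its 18 were the same windows in or at the edges of its large loss. The 7 of G15FN-54-3 overlapped its losses on chromosomes 10 and 16. The ranking thus reflects parts of losses left uncalled, and not scatter away from them.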

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

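The loss on the sequence named Chr014 was looked for only after the data were seen, and the comparison of opposite calls below involved no test. At 4 places a loss in 1 mutant overlapped a gain in another, and in each the difference was not tested, since each mutant had 1 array. On chromosome 15, 6 probes from 46867957 to 46871124 had a mean log2 ratio of −0.91 in G15FN-109-1, and an overlapping gain of 13 probes in G15FN-23-3 had a mean of 0.32. On chromosome 2, 10 probes from 31936042 to 31999589 had a mean of −0.54 in G15FN-109-1, and an overlapping gain of 7 probes in G15FN-54-3 from 31933577 to 31951899 had a mean of 0.58. The 10 probes had a mean of 0.27 in G15FN-54-3. On chromosome 3, 9 probes from 8619530 to 8635443 had a mean of −0.66 in G15FN-109-1, and a gain of 6 probes in G15FN-54-3 from 8617970 to 8621349, which overlapped their start, had a mean of 0.77. The 9 probes had a mean of 0.67 in G15FN-54-3. In the brighter channel, 16.7%, 20% and 22.2% of the probes of these 3 losses and 7.69%, 0% and 33.3% of those of the gains were above background. On chromosome 12, 7 probes from 20636043 to 20641420 lay inside the large loss of G15FN-12-1 at −4.59, and a gain of 7 probes in G15FN-23-3 had a mean of 0.38, with 85.7% of probes above background in the brighter channel.

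Among the 8054 probes placed on the sequence named Chr014, which no comparison above used, 1 loss was called. It lay in G15FN-109-1 from 47763851 to 47783544, with 8 probes, a mean of −0.67 (SD 0.63 over probes) and a mean of −0.08 on the other 3 arrays. The 29 probes of chromosome 14 at the same positions had a mean of −0.96 in that mutant but a median of −0.12, so a few low probes carried that mean. No Chr014 probe had the same start as a chromosome 14 probe, and the median distance to the nearest was 396 bp.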

How the results depend on the processing

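Of the alternatives below, the joining into regions, the placement of the Chr014 probes and the filter that kept segments with 50% of probes above background were chosen only after the result was seen. Counts are given in the order G15FN-109-1, G15FN-12-1, G15FN-23-3, G15FN-54-3 unless a mutant is named, and the main counts were 128, 154, 29 and 60 losses, 55, 12, 30 and 25 gains, and 6 shared losses. Of the counts and tail sums under other settings, 95 stayed close (counts within 1.5 times) and 83 moved; the cause was not tested for any of them. A penalty of 40 gave 84 losses in G15FN-109-1, and 25, 3, 5 and 7 gains. A penalty of 14 gave 110, 49, 63 and 47 gains. A minimum of 10 probes gave 31, 34, 18 and 14 losses, 18, 3, 5 and 3 gains, and 1 shared loss. A minimum of 3 probes gave 241, 98 and 63 losses in the first 3 mutants, 110, 46, 76 and 86 gains, and 10 shared segments. Thresholds of −0.8 and 0.5 gave 77 losses in G15FN-109-1 and 19 in G15FN-23-3, 34, 3, 10 and 9 gains, and 2 shared segments. Thresholds of −0.35 and 0.2 gave 77 losses in G15FN-23-3, 24 gains in G15FN-12-1 and 43 in G15FN-54-3.

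Normexp background correction gave 54 losses in G15FN-109-1, 31, 3, 4 and 0 gains, and 2 shared segments. It moved the sum of the values bounding the lowest and the highest 0.1% of probes from −0.59 to −0.32 in G15FN-109-1, from −5.56 to −2.04 in G15FN-12-1 and from −1.2 to −0.51 in G15FN-54-3. It turned the gain of G15FN-12-1 on chromosome 15 from 46941257 from 0.35 to −0.14, the only reversal among the 45 regions with at least 20 probes. The authors' value table gave 20 gains in G15FN-12-1. Without probes dim in the wild type there were 72 losses in G15FN-109-1, and 4, 9 and 1 gains in the last 3 mutants. The hidden Markov model gave 66, 12, 14 and 14 losses, 25, 2, 1 and 1 gains, and 3 shared segments. Without shrinkage there were 47, 43 and 18 losses in G15FN-109-1, G15FN-12-1 and G15FN-54-3, and 31 and 5 gains in G15FN-109-1 and G15FN-54-3. Subtracting each probe's median over the other 3 arrays gave 25 gains in G15FN-12-1, 49 in G15FN-54-3 and 0 shared segments, a count that the subtraction fixes, since a loss shared by 3 arrays is present in 2 of the 3 other arrays whose median is taken. Without joining there were 257, 48 and 97 losses in the last 3 mutants. Joining before the probe minimum gave 26 losses in G15FN-12-1 and 20 in G15FN-54-3. The filter on segments gave 78 losses in G15FN-109-1, 7 gains in G15FN-12-1 and 9 in G15FN-54-3. With windows of 50 probes the wide windows numbered 261, 181, 156 and 177 in place of 57, 31, 12 and 18, and with a ratio of 2 they numbered 14, 18, 2 and 7.

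The share of gains among the calls was 50.8% in G15FN-23-3 and 29.4% in G15FN-54-3. Normexp moved it to 12.1% and 0%, and subtracting the other arrays' medians to 62.7% and 49.0%. Leaving out the centring or the saturated spots moved no share by more than 1 point. The hidden Markov model moved it to 6.67% in both mutants. Joining before the probe minimum moved it to 55.6% in G15FN-54-3, and from 7.23% to 31.6% in G15FN-12-1, whose loss counts are largely fragments. Of these 45 regions, all were called at least in part without centring, without saturated spots and with the authors' value table. In each case 33 were called over at least 50% of their length. The regions came from the second way of calling, while these settings used the planned calling, which breaks deep losses into fragments. A count under 45 therefore need not come from the setting. Without probes dim in the wild type 41 were called in part and 28 over 50%, with normexp 36 and 32, without shrinkage 33 and 21, and with the hidden Markov model 39 and 37. A minimum of 10 probes gave 36 and 29, thresholds of −0.8 and 0.5 gave 39 and 24, and subtracting the other arrays' medians gave 41 and 25. When the mean of each region was taken again from its own probes, 42 stayed past the threshold without dim probes and 38 with normexp. After subtraction of the other arrays' medians 43 did. The 2 others were losses of G15FN-23-3 on chromosome 12, from 24273021 (−0.58 to −0.25) and from 27944169 (−0.64 to −0.13). Without dim probes the gains of G15FN-109-1 from 44378667 on chromosome 3 and from 39573431 on chromosome 2 fell from 0.76 to 0.17 and from 0.38 to 0.16, and its gain from 36067249 fell from 4.69 to 2.80. Signal over background limits the deep losses, whose depth is a bound, and the gains, many of which rest on dim wild-type probes. No paired analysis was possible because each mutant has 1 array. The overlap with gene lists and its alternatives (any overlap of a gene, and other thresholds) were not run, since no gene positions on the array's build were used here.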

Other observations

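Of the tests in this part, only the share of deviating probes per area of the slide and the calls in shuffled probe order were chosen before their results were seen, and all others after, some of them in place of earlier tests whose values had also been seen. Short, deep changes of G15FN-109-1 also lay outside the chromosomes described so far. On chromosome 16, 17 probes from 28901337 to 28908153 had a mean log2 ratio of −5.31 (SD 1.77 over probes), with all wild-type probes and 29.4% of mutant probes above background. On chromosome 14, 5 probes from 47779346 to 47782348 had a mean of −4.04 (SD 2.80), at positions within the span of the Chr014 loss described above. High values lay on chromosome 18 from 4176798 to 4178655 (5.70, 5 probes) and on chromosome 2 from 39299979 to 39307637 (4.16, 10 probes), where 20% and 50% of wild-type probes were above background. These 4 are regions, and all 8 gain regions with a mean of 2 or higher lay in this mutant, with 0 on the other 3 arrays. The planned calling gave 5 such gain segments, all in this mutant.

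Of 17 loss regions with a mean above −2 and at least 20 probes that were near 0 on the other arrays, 13 were picked by a median between −1.1 and −0.7 and an SD over probes under 0.5. Their medians lay between −0.99 and −0.89, and together they covered 4.41 Mb. The other 4 had medians of −0.58, −0.77, −0.21 and −0.94 with SDs of 1.92, 0.53, 2.21 and 0.93. The 13 fell on G15FN-109-1 (4 of its 8), G15FN-12-1 (3 of 3) and G15FN-23-3 (6 of 6), and 0 on G15FN-54-3. The other 4 were all on G15FN-109-1.

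A complete loss may be masked by cross-hybridisation, and probes above background in complete losses of the same arrays had an SD of at least 1.62. The 17 losses formed 11 clusters with a median SD of 0.40, which argues against masking that differs from probe to probe, except in the 2 widest, while masking alike at all probes was not tested. Wild-type DNA mixed into the mutant's sample would cap every loss of that sample, yet each of the 3 mutants also had a region at −4.84 or lower. Loss of 1 of 2 copies asks for a narrow range near −1. Counted as clusters, 63.6% of the losses had it, 7 of 11, fewer than the 75% set for it. All clusters without it lay in G15FN-109-1, and every cluster of G15FN-12-1 and G15FN-23-3 had it. As the share was set over all mutants, this explanation stays open too. So does a leaf of mixed cells, which was not tested.

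The opposed calls on chromosome 3 of G15FN-109-1 were weighed against 2 technical explanations. The fullest of 16 equal tiles of the slide held 8.15% of the deviating probes, where an even spread gives 6.25%, which argues against a damaged area. Of the 63 segments, 7.94% were dim in both channels, which argues against dim probes as the whole cause. Different sequence in the mutant and the wild-type plant was looked at through the 3 gain segments on the chromosome with a mean of 2 or higher. They are part of the pattern itself, so they cannot decide for it, and it stays open.

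The 67 gains on the 3 arrays with G00-3213 were short, with a median of 6 probes, 5.02 kb and a log2 ratio of 0.42. Runs of independent noise do not explain them, since shuffled probe order gave 1.94% as many. Shuffling also removes the correlation between neighbouring probes outside called segments, so runs of correlated noise were not tested. That correlation was 0.60 in G15FN-12-1, 0.14 in G15FN-23-3 and 0.43 in G15FN-54-3. In G15FN-12-1 and G15FN-54-3 it includes probes of the large losses that the planned calling left out. Called segments covered 39.9% of the block on chromosome 12 and 36.7% of that on chromosome 10. The correlation of the background alone was not measured there. A probe effect common to all arrays exists, since outside called segments every 2 arrays were correlated (r from 0.21 to 0.46), and after subtraction of the other arrays' medians 20 of the 67 were called again, among 111 gains in all. Only 20.9% of the gains had a mean on the other 3 arrays of at least 50% of their own, which argues against it as the whole cause but not as part. Dim probes stay open. In 47.8% of the gains fewer than 50% of wild-type probes were above background. Without probes dim in the wild type 14 gains were called on these arrays in place of 67. Normexp left 3 in G15FN-12-1, 4 in G15FN-23-3 and 0 in G15FN-54-3. How much of the gains dim probes account for is not settled, and no biological explanation was tested.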
